A study of Rattus norvegicus with 58 samples.

How the data were processed

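RNA was sequenced from skeletal muscle, uninvolved mammary gland and mammary tumour of female rats bred for high inherent aerobic capacity (HIAC) or low inherent aerobic capacity (LIAC). Per the labels' protocols, the tissues were snap frozen. RNA of gland and muscle was isolated with Qiazol and a column kit, and RNA of tumours with the column kit and a proteinase K digestion but no stated Qiazol step, so extraction and tissue cannot be told apart in a comparison of tumour with gland. Libraries were made with the Nugen Universal mRNA kit, per the labels' protocols. Reads were handled with fastp 0.20.0, HISAT2 2.1.0 and featureCounts 1.6.4, per the submitters' processing notes. The genome build, the annotation release and the strand setting of the counting were not given in the sources used here. Genes that overlap or lie antisense to one another may therefore share reads, and coordinates below are those the deposited files print, in an unnamed build.

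The authors deposited whole-number read counts per gene, not normalized, for each of the 58 samples, with chromosome, exon starts and ends, strand and length of each gene. A series table of the same counts differed from the per-sample files in 0 values. The files list 32883 genes, of which 25753 had at least 1 count in any library. Total counts per library ran from 19119537 to 67363222. All genes are given by Ensembl identifiers. The files do not pair these identifiers with gene names, and the reference table of gene names used here pairs 0 of them with a symbol. For this reason the 35 gene lists fixed by symbol before the data were examined, among them the renin-angiotensin system and the cell type markers, could not be matched and are not analysed here. Genes are described by position, and at most 2 identifiers of higher genes and 2 of lower genes are printed.

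Groups were taken from the labels, with 10 HIAC and 10 LIAC muscle samples, 12 HIAC and 10 LIAC gland samples, and 8 HIAC and 8 LIAC tumour samples. Replicate numbers follow the order of deposition and pair nothing. The labels do not say whether samples came from separate animals, or which tissues came from the same animal, so p-values measure the spread between these samples. The lowest chi-square per degree of freedom between any pair of libraries within a group, over genes with at least 20 counts in the pair, was 41.8, so no pair agreed within sampling noise. Tumour titles run from 1 to 8 and from 13 to 20, with both strains in each run. Gland titles run from 22 to 33 in HIAC and from 34 to 43 in LIAC, and muscle titles from 85 to 94 and from 95 to 104. In gland and muscle an effect that follows title order therefore cannot be told apart from strain.

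Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) after TMM normalization and the filterByExpr filter, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each strain comparison (HIAC minus LIAC) used the samples of its tissue. Tumour minus gland was averaged over the strains with equal weight, with 1 mean per group. Differences of strain effects between tissues came from 1 fit of the 58 samples. Standard errors (SE) of log2 fold changes are the log2 fold change divided by the square root of F. CPM denotes counts-per-million values after TMM scaling, and log2 CPM used a prior count of 2. The rule for named genes took those with the smallest p in each direction among genes past the threshold with a group mean of at least 1 CPM. Its condition of an assigned symbol could not be applied, and 2 genes per direction are described in place of 10.

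Gene groups were defined after the data were examined: muscle-, gland- and tumour-enriched genes (mean log2 CPM above 3 in that tissue and more than 3 log2 units above both other tissues), the 15 mitochondrial genes of at least 200 bp, and the genes of chromosomes 1 to 20 and X. They were tested with camera (limma 3.58.1) with an inter-gene correlation preset at 0.01, and also with an estimated correlation and with fry. The tissue-enriched sets were picked from these libraries and are not independent evidence of a difference between tissues. Shares of counts were compared by two-sided permutation tests on the log2 scale, exact for 8 against 8 tumours (12870 arrangements) and with 100000 permutations otherwise. The smallest p these can give is 1e-05. Wilson 95% intervals of shares cover counting error only.

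Alternatives fixed before the data were examined were RLE size factors, no expression filter, DESeq2 1.42.0, limma-voom with sample quality weights, removal of the 20 most abundant and the mitochondrial genes, 1 fit of the 58 samples, leaving out each library of a tissue in its strain comparison, the run of tumour title numbers, and each strain alone. Added after seeing the data were 2 surrogate variables (sva 3.50.0), the muscle-enriched share as a covariate, separate fits per tissue for the differences, fits of the differences without each of 3 doubtful libraries and without all 3, and fits of tumour against gland without each of 3 libraries. The edgeR step was tested on simulated counts for the measured genes with known changes. In the muscle simulation over 14464 genes it recovered 77 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, in the gland simulation over 15532 genes 74 and 93, and in the tumour simulation over 15316 genes 62 and 89. Of the genes called, 1.12%, 4.57% and 2.58% were unchanged ones. For tumour against gland, over 16786 genes, 86 and 97 of 100 were recovered with 5.67% of calls unchanged, and for the difference between tumour and gland, over 17212 genes, 54 and 90 with 5.26%. Changed genes were drawn only from those with a mean of at least 1 CPM, in each tissue for the difference, so recovery at lower levels was not tested. Simulated counts of different genes were drawn independently, and simulated libraries held no RNA of another tissue. In the real libraries exchanged strain labels called up to 220 genes for the difference between tumour and gland. The 5.26% therefore cannot be taken as the rate for that difference in the real libraries. The differences of muscle from gland and from tumour were not simulated. Figures were drawn with matplotlib 3.10.9.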

Results

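The series compared rats of 2 breeding lines that differ in inherent aerobic capacity, the exercise capacity of an animal without training. Its title links high capacity to low breast cancer risk and to the renin-angiotensin system. Counts per gene were given for 58 libraries from skeletal muscle, uninvolved mammary gland and mammary tumour. Muscle libraries held 42350055 to 67363222 counts, gland libraries 26565642 to 35600479, and tumour libraries 19119537 to 45651377. The 10 most abundant genes took 27.7% ± 3.57 (SD, n = 10) of counts in HIAC muscle and 26.0% ± 1.11 (n = 10) in LIAC muscle, 11.97% ± 4.55 (n = 12) and 12.5% ± 4.13 (n = 10) in gland, and 5.56% ± 0.717 (n = 8) and 5.91% ± 0.800 (n = 8) in tumour.

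In skeletal muscle, HIAC rats differed from LIAC rats in 188 of 14658 genes tested, 95 higher and 93 lower. The changes were mostly below 2-fold, with 69 called genes beyond it and a median absolute log2 fold change of 0.72. At an unadjusted p under 0.05 there were 2643 genes, against 733 expected by chance. The higher gene with the smallest p lay on chromosome 1 (201981357 to 202021008, plus strand, 12 exon blocks). It stood at 90.7 ± 21.8 CPM (SD, n = 10) in HIAC and 34.9 ± 3.61 CPM (n = 10) in LIAC muscle, a log2 fold change of 1.38 (SE 0.13, edgeR adjusted p = 4.88e-06), and 10 of 10 HIAC libraries were above every LIAC library. A gene on chromosome 10 (82338449 to 82341368, plus strand, 2 exon blocks) was nearly absent from LIAC muscle, at 0.0677 ± 0.0807 CPM with 0 counts in 3 of 10 libraries, and stood at 6.89 ± 3.66 CPM in HIAC muscle (log2 fold change 6.61, SE 0.70, adjusted p = 2.57e-05). It was above every LIAC library in 9 of 10 HIAC libraries. Its adjusted p was 0.0613 with limma-voom and sample quality weights.

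Among the lower genes in HIAC muscle, ENSRNOG00000014798 on chromosome 3 (80095042 to 80349145, minus strand, 9 exon blocks) had the smallest p. It fell from 13.6 ± 1.31 CPM in LIAC to 8.22 ± 0.420 CPM in HIAC muscle (log2 fold change -0.72, SE 0.06, edgeR adjusted p = 3.43e-06). A gene on the X chromosome (40363646 to 40415109, plus strand, 11 exon blocks) was at 10.0 ± 0.869 CPM in HIAC and 16.5 ± 2.93 CPM in LIAC muscle (log2 fold change -0.72, SE 0.09, adjusted p = 3.33e-04). For both genes 10 of 10 HIAC libraries were below every LIAC library. In gland and tumour neither passed the threshold (adjusted p from 0.0914 to 0.717), with log2 fold changes of -0.47 and -0.53 for ENSRNOG00000014798 and -0.24 and -0.49 for the X chromosome gene.

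As a group, the 15 mitochondrial genes of at least 200 bp were all above 0 in HIAC minus LIAC muscle, with a median log2 fold change of 0.30. With edgeR 0 of them were called and 5 had an unadjusted p under 0.05, with DESeq2 0 and with limma-voom 2 were called (camera adjusted p = 0.0022, but adjusted p = 0.962 with an estimated correlation). Mitochondrial genes took 19.3% ± 4.00 (SD, n = 10) of counts in HIAC and 16.3% ± 1.91 (n = 10) in LIAC muscle, a difference that did not pass the threshold (permutation p = 0.0777, BH adjusted 0.222 over 20 tests of shares). HIAC replicate 8, at 11.58%, had the lowest share of all muscle libraries. HIAC replicates 9 and 10, next in title order, were at 15.37% and 15.64%. HIAC replicates 1 to 7 ran from 18.95% to 24.51%, and the LIAC libraries from 12.95% to 19.85%. This share was not tested without HIAC replicate 8. Muscle-enriched genes had a median log2 fold change of -0.12, with 6 of 490 called lower and 0 higher (camera adjusted p = 1.27e-06, but adjusted p = 0.962 with an estimated correlation). Their share of counts was 38.2% ± 3.77 in HIAC and 41.5% ± 2.98 in LIAC muscle (permutation p = 0.0357, BH adjusted 0.119). HIAC replicate 8 had a muscle-enriched share of 28.3% (Wilson 95% interval 28.28 to 28.30) against 37.8% to 42.5% in the other HIAC libraries. Without it 324 genes were called, 172 higher and 152 lower. Nuclear genes with 1 exon block took less of the counts in HIAC muscle, 0.960% ± 0.0620 against 1.13% ± 0.148 (permutation p = 0.00251, BH adjusted 0.01).

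In uninvolved mammary gland, 49 of 15899 genes differed between the strains, 32 higher and 17 lower in HIAC. Of these, 34 changed more than 2-fold. An unadjusted p under 0.05 was found for 1647 genes, against 795 expected by chance. ENSRNOG00000042912 on chromosome 10 (82232107 to 82252963, minus strand, 20 exon blocks) was the higher gene with the smallest p, at 18.5 ± 6.62 CPM (SD, n = 12) in HIAC and 3.59 ± 1.58 CPM (n = 10) in LIAC gland (log2 fold change 2.36, SE 0.29, edgeR adjusted p = 3.63e-04). A gene on chromosome 9 (46840992 to 46881264, plus strand, 9 exon blocks) followed, at 58.9 ± 23.8 against 13.3 ± 5.37 CPM (log2 fold change 2.15, SE 0.31, adjusted p = 0.00259). Both were above every LIAC library in 11 of 12 HIAC libraries. In 1 fit of the 58 samples the adjusted p of the chromosome 9 gene in gland was 0.117. The chromosome 9 gene did not pass the threshold in muscle (log2 fold change 1.88, adjusted p = 0.221, and 1.11 without HIAC replicate 10) or in tumour (2.06, adjusted p = 0.469, with 0.92 without HIAC replicate 6 and 3.54 without LIAC replicate 8).

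ENSRNOG00000027271 on chromosome 10 (95642640 to 95657977, plus strand, 5 exon blocks) was the lower gene with the smallest p in HIAC gland, at 29.0 ± 26.9 CPM against 192 ± 61.9 CPM in LIAC gland (log2 fold change -2.73, SE 0.39, adjusted p = 0.00259). It was below every LIAC library in 12 of 12 HIAC libraries. On chromosome 20 a gene (30915213 to 30921382, plus strand, 4 exon blocks) was at 2.73 ± 1.29 CPM in HIAC and 11.4 ± 8.53 CPM in LIAC gland (log2 fold change -2.06, SE 0.34, edgeR adjusted p = 0.00878). It was below every LIAC library in 7 of 12 HIAC libraries.

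Gland-enriched genes had a median log2 fold change of 0.12 in HIAC gland, with 2 of 92 called higher (camera adjusted p = 2.69e-04, but adjusted p = 0.989 with an estimated correlation). Tumour-enriched genes had a median of -0.60, with 0 of 214 called by edgeR, 1 by DESeq2, 1 by limma-voom and 15 at an unadjusted p under 0.05 (camera adjusted p = 2.69e-04, but adjusted p = 0.989 with an estimated correlation). Their share of counts was 0.249% ± 0.172 (SD, n = 12) in HIAC and 0.407% ± 0.285 (n = 10) in LIAC gland, which overlapped (permutation p = 0.269). Mitochondrial genes took 8.39% ± 2.88 and 8.90% ± 3.18 (permutation p = 0.627). In LIAC replicate 5 muscle-enriched genes took 6.67% of counts (Wilson 95% interval 6.66 to 6.68), against 0.841% to 1.76% in the other LIAC gland libraries. Without that library 28 genes were called.

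In mammary tumours, 10 of 15438 genes differed between the strains, 5 in each direction, and 7 of them by more than 2-fold. There were 1719 genes at an unadjusted p under 0.05, against 772 expected by chance. DESeq2 called 222 genes. A gene on chromosome 2 (195861649 to 195908037, minus strand, 13 exon blocks) had the smallest p. Its level was 23.5 ± 2.88 CPM (SD, n = 8) in HIAC and 11.9 ± 1.35 CPM (n = 8) in LIAC tumours (log2 fold change 0.98, SE 0.10, edgeR adjusted p = 2.61e-04). In tumours ENSRNOG00000042912 was again higher in HIAC, at 22.5 ± 7.24 against 5.47 ± 2.04 CPM (log2 fold change 2.04, SE 0.26, adjusted p = 0.00311). For both genes 8 of 8 HIAC libraries were above every LIAC library. A gene on chromosome 6 (136276057 to 136279399, minus strand, 2 exon blocks) was at 0.197 ± 0.102 CPM in HIAC and 1.02 ± 0.135 CPM in LIAC tumours (log2 fold change -2.34, SE 0.29, adjusted p = 0.00311), with 8 of 8 HIAC libraries below every LIAC library. Its adjusted p was 0.0571 in 1 fit of the 58 samples. It was also called lower in HIAC muscle (log2 fold change -3.06, SE 0.52, adjusted p = 0.00476), and without muscle LIAC replicate 1 the value was -2.35 (adjusted p = 0.00262). A gene with 1 exon block on chromosome 7 (121342679 to 121343013, plus strand) was at 0.326 ± 0.143 against 3.39 ± 1.87 CPM (log2 fold change -3.36, SE 0.52, adjusted p = 0.0245), and 1 of 8 HIAC libraries was below every LIAC library, LIAC replicate 8 being at 0.2295 CPM. This call was lost with limma-voom, with 2 surrogate variables and in 8 of 16 fits without 1 tumour library, with adjusted p up to 0.109. Its log2 fold change ran from -3.56 to -2.96 over all refits.

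Tumour-enriched genes took 3.40% ± 0.369 (SD, n = 8) of counts in HIAC and 3.15% ± 0.678 (n = 8) in LIAC tumours (exact permutation p = 0.301). Within the tumours of titles 1 to 8 these shares were 3.53% ± 0.210 (n = 4) and 3.43% ± 0.790 (n = 4; exact permutation p = 0.743), and within those of titles 13 to 20 they were 3.26% ± 0.476 (n = 4) and 2.87% ± 0.4926 (n = 4; exact permutation p = 0.286, with 0.0286 the smallest p possible). Gland-enriched genes had a median log2 fold change of -0.75 in HIAC tumours with 0 of 72 called by edgeR, 1 by DESeq2, 0 by limma-voom and 16 at an unadjusted p under 0.05 (camera adjusted p = 2.37e-05, but adjusted p = 0.765 with an estimated correlation). Their share of counts went opposite ways in the runs, at 0.0871% ± 0.0327 in HIAC (n = 4) and 0.224% ± 0.155 in LIAC tumours (n = 4) of titles 1 to 8 (exact permutation p = 0.171) and at 0.168% ± 0.0994 and 0.146% ± 0.125 in those of titles 13 to 20 (exact permutation p = 0.571). Muscle-enriched genes had a median of -0.57 with 0 of 344 called by edgeR, 10 by DESeq2, 0 by limma-voom and 126 at an unadjusted p under 0.05 (camera adjusted p = 2.75e-07, but adjusted p = 0.852 with an estimated correlation). In LIAC replicate 7 muscle-enriched genes took 9.86% of counts (Wilson 95% interval 9.85 to 9.87), against 0.841% to 1.58% in the other LIAC tumours, and without it 5 genes were called. X chromosome genes had a median of -0.07 with 0 of 524 called by edgeR, 5 by DESeq2, 1 by limma-voom and 52 at an unadjusted p under 0.05 (camera adjusted p = 0.019, adjusted p = 0.765 with an estimated correlation). Without LIAC replicate 6, which stood apart in X chromosome counts, the camera p for X was 0.171. With the run of title numbers as a term, 6 genes were called.

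Strain differences were compared across tissues, since the lines differ in all of them. Genes called in muscle had the same sign in gland for 136 of 178 genes (76.4%) and in tumour for 120 of 173 (69.4%). Genes called in gland had the same sign in muscle for 36 of 48 and in tumour for 34 of 47. In both muscle and gland 8 were called, against 0.305 expected of independent lists, 4 in both muscle and tumour against 0.0564, and 3 in both gland and tumour against 0.0157, each in the same direction in both tissues. A score of the genes called in muscle, signed by their direction there, differed between HIAC and LIAC gland by 0.48 SD units (permutation p = 1e-05, the smallest these can give), with 11 of 12 HIAC libraries above 0 and 10 of 10 LIAC libraries below 0. Between HIAC and LIAC tumours it differed by 0.38 (exact permutation p = 0.00326), and 7 of 8 HIAC libraries were above 0 and 6 of 8 LIAC libraries below 0. The score of the genes called in gland differed in muscle by 0.69 (permutation p = 1e-05), with 10 of 10 HIAC libraries above 0 and 10 of 10 LIAC libraries below 0. The permutations and the expected numbers take the tissues as independent. The labels do not say which tissues share an animal, so differences between shared animals could also give such overlaps and scores. In muscle and gland an effect of title order cannot be told apart from strain.

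Across the 13792 genes tested in all 3 tissues, 3 were called in the same direction in each. They were ENSRNOG00000042912, ENSRNOG00000057645 and ENSRNOG00000027271, and 9.90e-05 would be expected of independent lists. ENSRNOG00000042912 was at 1.41 ± 1.03 CPM (SD, n = 10) in HIAC and 0.241 ± 0.207 CPM (n = 10) in LIAC muscle (log2 fold change 2.53, SE 0.60, edgeR adjusted p = 0.0403). ENSRNOG00000057645 on chromosome 1 (79754587 to 79772092, plus strand, 6 exon blocks) was higher in HIAC by log2 fold changes of 1.25 in muscle (SE 0.25, adjusted p = 0.016), 1.11 in gland (SE 0.19, adjusted p = 0.00878) and 1.29 in tumour (SE 0.22, adjusted p = 0.0457). ENSRNOG00000027271 was lower in HIAC muscle (log2 fold change -2.45, SE 0.44, adjusted p = 0.00804) and in HIAC tumours (-2.61, SE 0.45, adjusted p = 0.0457). The tumour calls of the last 2 genes lay close to the threshold, and they were lost in 14 of the 16 fits that left out 1 tumour library. Both were also lost with the run of title numbers as a term, with log2 fold changes of 1.29 and -2.61, and with no filter, surrogate variables or the muscle-enriched share as a term. The adjusted p in those fits and the other alternatives reached 0.123 and 0.117. The muscle call of ENSRNOG00000042912 was lost in 10 of 20 fits that left out 1 muscle library, and also with no filter and with limma-voom. Over its refits the log2 fold change ran from 2.34 to 2.88 and the adjusted p reached 0.105. The number of genes called in all 3 tissues ranged from 0 with no expression filter to 14 with DESeq2.

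**Figure D1:**
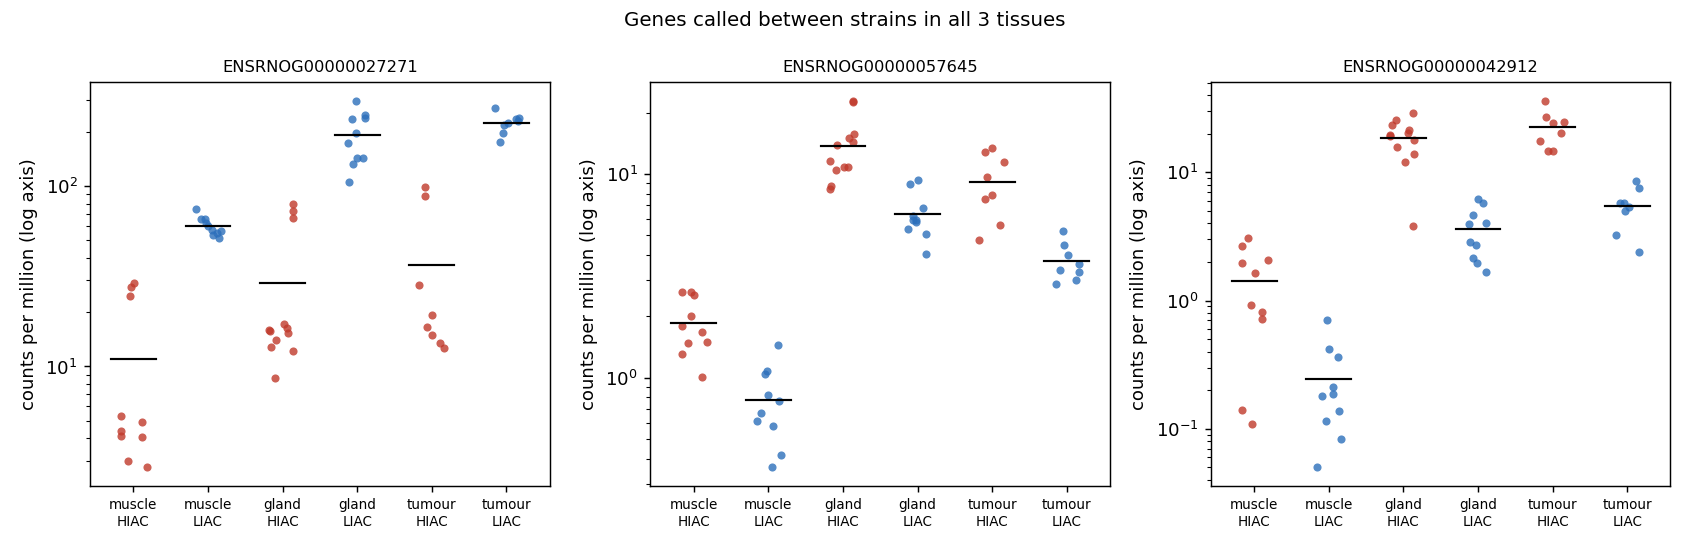
Counts-per-million values (CPM, log axis) of the 3 genes called between strains in all 3 tissues, 1 point per library and a line at each group's mean, with 1 LIAC muscle library at 0 counts drawn at 0.05. ENSRNOG00000027271 is below every LIAC library of the same tissue in all HIAC libraries, and its HIAC values fall apart into separate levels.

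Tumour was compared with uninvolved gland, and 11512 of 17048 genes differed, 5687 higher and 5825 lower in tumour. Of these, 5164 changed more than 2-fold, 2234 upward and 2930 downward. The higher gene with the smallest p lay on chromosome 1 (127301128 to 127337882, minus strand, 13 exon blocks), at 394 ± 127 CPM (SD, n = 16) in tumour and 22.6 ± 7.59 CPM (n = 22) in gland (log2 fold change 4.12, SE 0.19, edgeR adjusted p = 1.62e-18). A gene on chromosome 7 (26645422 to 26859716, minus strand, 4 exon blocks) was at 45.9 ± 11.7 against 9.82 ± 1.84 CPM (log2 fold change 2.23, SE 0.11, adjusted p = 1.87e-18). Another gene on chromosome 1 (146713676 to 146736261, minus strand, 14 exon blocks) was lower in tumour, at 9.90 ± 1.89 against 96.8 ± 30.9 CPM (log2 fold change -3.28, SE 0.15, adjusted p = 1.62e-18). On chromosome 3 a gene (80004130 to 80012750, minus strand, 9 exon blocks) was at 17.1 ± 3.91 in tumour against 186 ± 66.3 CPM in gland (log2 fold change -3.42, SE 0.16, adjusted p = 2.26e-18). For these 4 genes the ranges of the 16 tumour and 22 gland libraries did not overlap.

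Mitochondrial genes were lower in tumour as a group. All 15 of at least 200 bp were called lower, by log2 fold changes from -3.13 to -1.34 with a median of -2.24 (camera adjusted p = 7.18e-12, but adjusted p = 0.284 with an estimated correlation, and fry adjusted p = 1.45e-15). Genes of the mitochondrial chromosome took 2.49% ± 0.523 (SD, n = 16) of counts in tumour and 8.62% ± 2.96 (n = 22) in gland, with no overlap between the highest tumour (3.74%) and the lowest gland library (5.17%; permutation p = 1e-05, BH adjusted 5e-05). Nuclear genes with 1 exon block took 1.71% ± 0.0719 of counts in tumour and 1.37% ± 0.164 in gland (permutation p = 1e-05). RNA of tumours was extracted by another protocol, so these differences cannot be told apart from extraction. Against the other genes, no chromosome from 1 to 20 or X passed the threshold with camera (adjusted p from 0.555). With fry, which does not compare a group with other genes, 16 of the 21 chromosomes passed it, with median log2 fold changes over all 21 from -0.16 (chromosome 13) to 0.12 (chromosome 19).

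**Figure D2:**
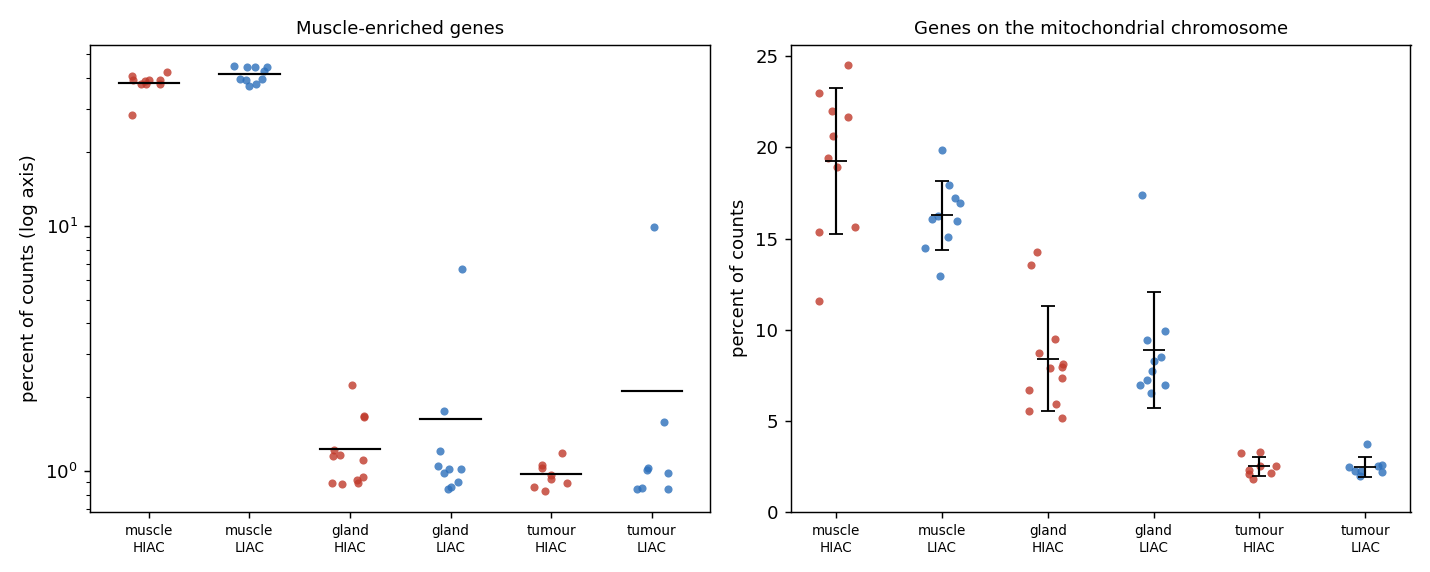
Percent of each library's counts in the 490 muscle-enriched genes (left, log axis, line at the mean) and in genes of the mitochondrial chromosome (right, mean with SD), 1 point per library. The mitochondrial share runs from 1.82% to 3.74% in tumour and from 5.17% to 17.4% in gland, and 1 LIAC gland library at 6.67% and 1 LIAC tumour library at 9.86% stand apart in muscle-enriched genes.

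Whether the strain effect differed between tissues was tested in 1 fit of the 58 libraries. It differed between tumour and gland for 13 of 17537 genes (3 higher and 10 lower in tumour), between muscle and gland for 331 (300 and 31), and between muscle and tumour for 74 (58 and 16). These counts are not beyond those of other splits of the same libraries, where strain labels exchanged within each tissue gave up to 220, 344 and 183 genes. Adjusted p-values of single genes from this fit, here and below, carry the same limit. Without muscle HIAC replicate 8 the count for muscle and gland was 18, and that for muscle and tumour was 22. Without gland LIAC replicate 5 the count for tumour and gland was 135, and that for muscle and tumour was also 135. The higher genes of muscle against gland, 300 of the 17537 tested, included 1 of the 490 muscle-enriched, 1 of the 92 gland-enriched and 20 of the 221 tumour-enriched genes. The gene with the smallest p between tumour and gland lay on chromosome 9 (50526811 to 50548046, 4 exon blocks), where the strain effect in tumour minus that in gland was -3.22 log2 units (SE 0.56, edgeR adjusted p = 0.00471). Between muscle and tumour it lay on chromosome 1 (215828102 to 215846911, 8 exon blocks), where the strain effect in muscle minus that in tumour was -7.92 log2 units (SE 1.31, adjusted p = 0.00239), or -9.17 (adjusted p = 1.54e-04) without tumour LIAC replicate 7. In the muscle samples alone that gene was lower in HIAC by a log2 fold change of -3.38 (adjusted p = 3.87e-04), and in the tumour samples alone its log2 fold change was 4.5, which did not pass the threshold (adjusted p = 0.327), with 3.01 without HIAC replicate 6 and 5.76 without LIAC replicate 7.

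**Figure D3:**
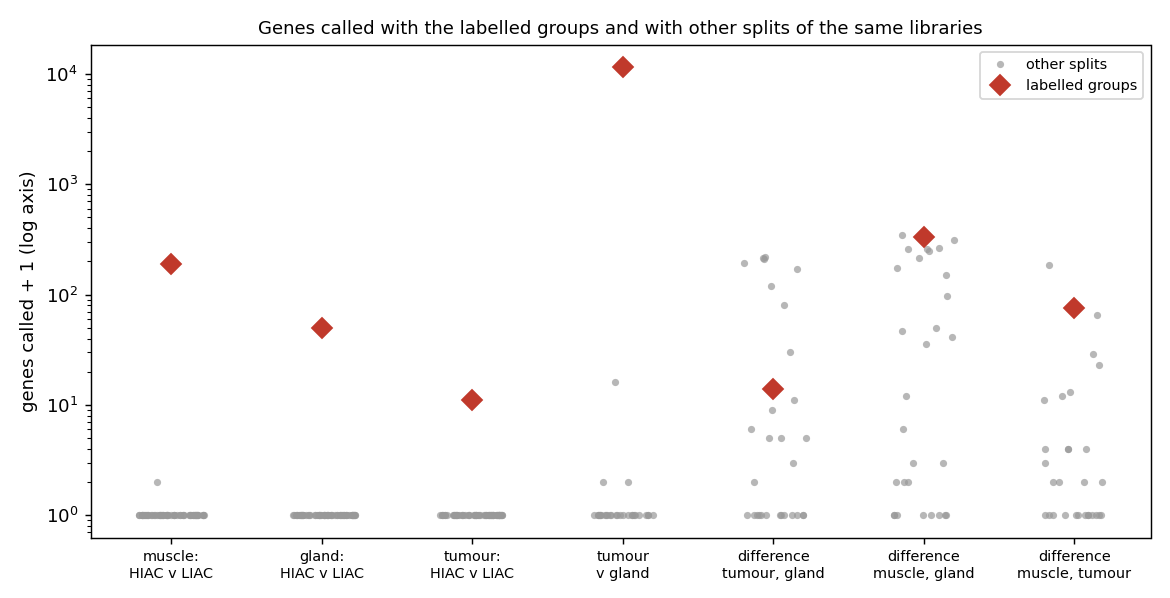
Number of genes called plus 1 (log axis) for the labelled groups (diamonds) and for other splits of the same libraries (grey points), per comparison. The 3 strain comparisons at 188, 49 and 10 genes and tumour against gland at 11512 lie above every other split drawn, while the 3 differences of strain effects lie within the range of the other splits.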

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

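The test of the X chromosome in tumour LIAC replicate 6 against normalization was chosen only after the result was seen, as were the lists of the same lengths in splits of the 3 tissues and the fits without 1 library for the differences, and the sets of tissue-enriched genes were defined after the data were examined. In 71 groups of values from 4 to 10 libraries, 16 highest or lowest values stood apart from the rest of their group, where chance gives about 3.55. Groups of 12 libraries were not examined in this way.

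Strain differences within each tissue were set against other splits of the same libraries. In muscle 188 genes were called, 1 of 60 splits (the real one) gave as many, and the highest other gave 1. In gland 49 were called in 1 of 60 splits, and the highest other gave 0. In tumour 10 were called in 1 of 60 splits, and the highest other gave 0. For tumour against gland 11512 genes were called in 1 of 30 splits, and the highest other gave 15. If the samples came from separate animals, chance can be excluded at that level for these 4 results. The labels do not say whether they did, and splits would part samples of the same animal. In gland and muscle each strain holds its own run of titles, so splits cannot part strain from an effect of title order there. For the 3 genes called in all 3 tissues 1 of 60 splits gave as many and the highest other gave 0, an outcome fixed by the other gland and tumour splits, which called 0 genes. Lists of the same lengths by smallest p, with each tissue split on its own, shared 3 genes in 1 of 60 splits, and the highest other gave 0. Independent lists would share 9.90e-05 genes in the same direction. The lists were compared in any direction, where the number expected is larger but still far below 1, so 0 in the other splits was all but fixed beforehand. The overlap is therefore beyond that of independent lists only. Splitting each tissue on its own also parts any animals shared between tissues, so an overlap from shared animals cannot be excluded. Chance cannot be excluded for the differences of strain effects: 9 of 30 splits gave at least the 13 genes of tumour against gland (highest other 220), 2 of 30 the 331 of muscle against gland (highest other 344), and 2 of 30 the 74 of muscle against tumour (highest other 183). For the difference of strain effects in tumour and gland the highest other split called 220 genes, against 13 with the real labels, and the reason was not tested.

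Muscle HIAC replicate 8 stood apart in 5 values. Muscle-enriched genes took 28.3% of its counts (37.8% to 42.5% in the other HIAC muscle libraries), gland-enriched genes 0.598% (0.041% to 0.178%), tumour-enriched genes 0.111% (0.0133% to 0.0331%) and the 10 most abundant genes 19.7% (25.9% to 31.9%). Its log2 CPM of the chromosome 1 gene at 201981357 to 202021008 was 5.45, against 6.12 to 6.88.

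The 331 genes with a different strain effect in muscle and gland, 300 of them higher in muscle, were the pattern weighed against these libraries. Skeletal muscle RNA in gland LIAC replicate 5 is argued against, since 0.333% of the higher genes belonged to the muscle-enriched set and 303 genes were called without that library. A strain effect in muscle itself met its written condition, with a median muscle log2 fold change of 2.12. That median covers 135 of the 300 higher genes, since the others did not pass the expression filter in muscle. But muscle HIAC replicate 8 sets that value: without it the median was 0.20, with 91 of 135 genes above 0 and 21 called. The genes were picked for a higher effect in muscle than in gland in these same libraries, which favours values above 0. The choice to leave this explanation undecided was made after 2.12 was seen, and an effect of that size shared by the other muscle libraries is argued against, while a smaller one stays open. RNA of another tissue in muscle HIAC replicate 8 is a candidate explanation, since 18 genes were called without that library, though a different state of that muscle sample would give the same count.

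Tumour LIAC replicate 6 had a median log2 difference of 0.37 from the other tumours over 395 X chromosome genes, a 1.29-fold higher level, where the other LIAC tumours had -0.071 to 0.051. Normalization or depth is argued against by the autosomes, whose largest absolute median was 0.034. Gland or muscle RNA is argued against by the X genes' median gland minus tumour difference of 0.00798 and muscle minus tumour difference of -0.12, and a few X genes with high counts by the 84.1% of X genes that were higher, with 13 of 13 windows of 10 Mb above 0. The library was picked by looking over all chromosomes and libraries, and no biological explanation was tested, so a change in X dosage in that tumour stays open as untested.

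Tumour LIAC replicate 7 had 9.86% of counts in muscle-enriched genes (0.841% to 1.58% in the other LIAC tumours) and 3.74% in mitochondrial genes (1.94% to 2.56%). Gland LIAC replicate 5 had 6.67% in muscle-enriched genes (0.841% to 1.76%). Gland LIAC replicate 3 had 17.4% in mitochondrial genes (6.54% to 9.94%) and 23.9% in its 10 most abundant genes (8.63% to 12.3%). High shares were also seen in HIAC gland, a group not examined in this way. There replicates 4 and 7 had 13.5% and 14.3% in mitochondrial genes and 21.8% and 20.6% in their 10 most abundant genes. Tumour HIAC replicate 6 had 0.310% in gland-enriched genes (0.0535% to 0.160%).

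Among single genes, the log2 CPM of the chromosome 10 gene at 82338449 to 82341368 was -2.09 in muscle HIAC replicate 7, against 1.26 to 3.43 in the other HIAC muscle libraries. That of the chromosome 9 gene at 46840992 to 46881264 was 1.88 in gland LIAC replicate 2, against 3.17 to 4.37. For the chromosome 7 gene at 121342679 to 121343013 it was -3.17 in tumour HIAC replicate 1, against -1.59 to -0.79, and -1.73 in tumour LIAC replicate 8, against 0.98 to 2.50. The chromosome 10 gene did not pass the expression filter in the gland samples or the tumour samples. Its strain effect was therefore not tested in those tissues alone, and differences from them rest on low counts there. In the fit of the 58 samples the strain effect of this gene was higher in muscle than in gland by 4.77 log2 units (edgeR adjusted p = 0.0182). It was higher in muscle than in tumour by 5.45 (adjusted p = 0.0375). Without muscle HIAC replicate 8 these were 4.87 (adjusted p = 0.0734) and 5.55 (adjusted p = 0.0489). That of the chromosome 20 gene at 30915213 to 30921382 was higher in muscle than in gland by 2.56 (adjusted p = 0.0456), a value that rests on muscle HIAC replicate 8, at 16.2 CPM against 0.334 to 1.24 CPM in the other HIAC muscle libraries. Without that library the difference was 0.89 (adjusted p = 0.676) and the gene was lower in HIAC muscle (log2 fold change -1.19, adjusted p = 0.042), and without gland LIAC replicate 5 the difference was 2.55 (adjusted p = 0.0541).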

How the results depend on the processing

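Tests with surrogate variables, the muscle-enriched share as a covariate, separate fits per tissue and fits without 3 libraries that stood apart were chosen only after the result was seen, as were the single fit of 58 samples for genes called in all 3 tissues and fits without 1 library for differences and for tumour against gland. Counts of called genes depended on the tool, and the cause was not tested. Muscle, with 188, gave 112 with no filter, 550 with DESeq2, 349 with limma-voom, 465 with 2 surrogate variables and 819 in 1 fit of 58 samples (645 higher, 174 lower). Gland, with 49, gave 233 with DESeq2, 133 with limma-voom, 105 with surrogate variables and 186 in 1 fit (79 higher, 107 lower). Tumour, with 10, gave 6 with no filter, 222 with DESeq2, 21 with limma-voom, 3 with surrogate variables, 6 with run as a covariate and 259 in 1 fit (60 higher, 199 lower). Tumour against gland ran from 7916 in LIAC samples alone to 13129 with no filter. For the difference of tumour and gland, with 13, the counts were 128 with DESeq2, 6 without 3 libraries and 1 with separate fits. That of muscle and gland, with 331, gave 781 with no filter, 16 with limma-voom, 12 without 3 libraries and 4 with separate fits. That of muscle and tumour, with 74, gave 112 with no filter, 319 with DESeq2, 40 with limma-voom, 17 without 3 libraries and 8 with separate fits. Genes called in all 3 tissues, 3 in number, were 0 with no filter, 14 with DESeq2, 12 in 1 fit, 1 with surrogate variables and 1 without 3 libraries.

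With 1 library left out, muscle gave 104 to 324. Counts of 104 to 124 came without HIAC replicates 3, 5, 7 and 9 or LIAC replicates 2, 3, 4, 5, 7 and 10, and 324 without HIAC replicate 8. Gland gave 21 to 69, with 21 to 31 without HIAC replicates 1, 2 and 5 or LIAC replicates 2, 5, 7 and 8. Tumour gave 4 to 10, with 4 to 6 without HIAC replicates 2, 3, 5, 6 and 7 or LIAC replicates 2, 3, 4 and 7. Other comparisons were refitted without only 3 libraries, 1 at a time. Tumour against gland gave 11414 to 11629 without tumour LIAC replicates 6 and 7 or gland LIAC replicate 5. Without muscle HIAC replicate 8, tumour LIAC replicate 7 or gland LIAC replicate 5 the differences gave 9 to 135 (tumour and gland, 135 without gland LIAC replicate 5), 18 to 342 (muscle and gland, 18 without muscle HIAC replicate 8) and 22 to 135 (muscle and tumour, 22 without muscle HIAC replicate 8 and 135 without gland LIAC replicate 5). In 529 refits of 22 named gene results 468 kept direction and call, 61 kept direction only and 0 reversed. Marker scores as covariates, the slow fibre score and the gene list tests were not run, since no symbols were paired with the identifiers. No paired analysis was possible because replicate numbers follow the order of deposition.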

Other observations

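The choice to leave linkage on a smaller scale undecided and the test on sets with planted neighbours were made only after the result was seen, as was the choice of the genes and regions named here.

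On chromosome 10, counts of ENSRNOG00000027271 fell into separate levels within HIAC. In muscle 7 HIAC libraries lay between 2.76 and 5.33 CPM and 3 between 24.7 and 29.2 CPM, and LIAC libraries began at 51.8 CPM. In gland 9 lay between 8.58 and 17.2 CPM and 3 between 66.8 and 79.7 CPM, with LIAC libraries from 105.7 CPM. In tumour 6 lay between 12.7 and 28.5 CPM and 2 between 88.4 and 98.8 CPM, with LIAC libraries from 176.5 CPM. The labels do not tie libraries of different tissues to an animal.

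Joined over gaps of at most 1 Mb between neighbours, 31 of the 235 genes called in any tissue formed 10 groups of at least 3. In 5 of the groups the genes went both ways, as on chromosome 19 (24467964 to 26094756), where 2 of 4 were higher in HIAC, and 3 of the 5 others follow. On chromosome 6 (136005823 to 136373721) 3 genes were lower in HIAC muscle, by log2 fold changes of -0.60, -3.06 (-2.35 without muscle LIAC replicate 1) and -0.51. On chromosome 1 (215515764 to 215846911) 3 genes were lower in HIAC muscle, by -1.16, -1.82 and -3.38, and their log2 fold changes in tumour were 0.86, 1.52 and 4.5, none of them called by edgeR. The last 2 of these were -0.31 and 3.01 without tumour HIAC replicate 6, and 3.63 and 5.76 without tumour LIAC replicate 7. On chromosome 20 (29509289 to 29738506) 3 genes were higher in HIAC in the tissue that called them, 2 in muscle (2.30 and 1.15) and 1 in gland (1.06). In tumour, where none was called by edgeR, the first 2 were at 0.47 and 0.51 and the last at -0.66. That last value was -1.38 without tumour HIAC replicate 2 and 0.55 without tumour LIAC replicate 3. On chromosome 10 a pair of genes higher in HIAC muscle lay at 82232107 to 82252963 and at 82338449 to 82341368.

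The hypothesis that linked stretches of the genome differ between the lines was set against these positions. Called genes formed 54 pairs within 1 Mb, against 45.0 on average in random sets of tested genes (p = 0.144 over 10000 sets). This was no excess over random sets and met the condition written beforehand against the hypothesis. Simulated sets with 40 planted neighbours gave 83.7 pairs on average and 100 of 100 exceeded 58 pairs, the 95th percentile of random sets. The 54 pairs of the called genes lay below that, so linkage on the planted scale is argued against. The test was not shown to see less, so linkage on a smaller scale stays open. Without pairs under 10 kb apart p was 0.151, so reads shared by overlapping genes could not be tested for want of an excess. In 51 of 60 splits of the libraries, lists of the same lengths gave as many pairs (highest other 84), so neighbouring genes that vary together in any split may give such pairs.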
